A study of Homo sapiens with 6 samples.

How the data were processed

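Messenger RNA was sequenced from U937 cells, a human myeloid line usually described as a histiocytic lymphoma line with monocytic features, which the labels class as an acute promyelocytic leukaemia cell. Of the 6 libraries, 3 were labelled as controls and 3 as overexpressing BCL6B, and all 6 carried the same batch label. Per the labels' protocols, RNA was selected with oligo(dT) beads, fragmented and made into dUTP-marked, strand-specific libraries. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

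The values used are FPKM (fragments per kilobase of gene length, scaled to library depth), deposited by the authors as 1 column per library with a gene length column, per the file headers. Adapter trimming with cutadapt 1.9 and genome build GRCh38 are named in the submitters' processing notes. The aligner, the read counter, the treatment of reads that match several places and the use of strand in counting are not given in the sources used here. Coordinates are those of the deposited table.

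The table listed 58735 genes. Multiplying each FPKM value by the gene's length gave a whole multiple of 1 step per library for 100% of the 139702 values above 0, within a tolerance of 0.01. The reads per gene and the library totals behind the FPKM could therefore be worked out. Reads in listed genes ranged from 16481014 in control replicate 3 to 18870186 in overexpression replicate 3, which was 94.2% to 96.8% of the totals the authors divided by. For a gene with no read, the level that a count of 0 allows was taken as 3 counts. This limit covers counting error only, because PCR copies without molecular identifiers are not independent molecules.

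Genes with an FPKM of at least 0.5 in at least 3 of the 6 libraries were tested, which left 14662. The groups were compared on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, with a mean-variance trend and Benjamini-Hochberg adjustment over all tested genes at a threshold of 0.05. A log2 change is on this scale and understates the change of genes with low values. For BCL6B, GGT5 and BCL6, a two-sided exact permutation test was added. With 3 libraries against 3 its smallest possible p is 0.1. All comparisons are two-sided.

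Before the data were examined, 40 gene lists were fixed, covering the processes named in the study's title and design, myeloid differentiation, other cell types and RNA quality. The 34 lists with at least 5 tested members were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists. The genes named in the text follow a rule also fixed beforehand. It takes BCL6B, GGT5 and BCL6, then the 10 protein-coding genes with the largest rise and the 10 with the largest fall among those that passed, were fully separated between groups and had a mean FPKM of at least 1 in the higher group. From each list that camera called it takes the up to 4 members with the smallest adjusted p in the list's direction, and from every other list the up to 3 members with the smallest adjusted p that passed. For each list the count of members that passed is also given adjusted over the list alone. Some genes that the rule takes are not reported here. Genes named outside the rule are said to be so.

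Alternatives were the pseudocount (0.1 and 0.5), the filter (none, or a mean FPKM of at least 1), scaling by median ratio, quantile normalization, rescaling to TPM, no mean-variance trend, library weights, the replicate number as a block, limma voom on the recovered reads, an estimated correlation in camera, other thresholds and leaving out each library. A spline correction on GC content and gene length, and a restriction to genes of at least 200 bases, were added after the data were seen. GC content came from the longest GENCODE 29 transcript of each gene. Tested genes that the rule takes were checked with BLAST+ 2.17.0 for copies of at least 98% identity over 200 bases. They were also checked for exons shared with other genes over at least 20% of their length. BCL6 and genes named outside the rule were not checked.

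The procedure was tested on simulated reads with the real means and library totals and 200 changed genes, in a comparison of 14772 tested genes. It recovered 8% of 50 genes changed 1.25-fold, 42% of 50 changed 1.5-fold, 68% of 50 changed 2-fold and 91.5% of 47 changed 4-fold, with 11 calls among 14575 unchanged genes. Small changes were therefore missed more often. The simulation changed far fewer genes than the 2687 called in the real data. It also used 1 dispersion of 0.00459 for all genes and no shift shared by the genes of a library. Its rates of recovery and of false calls therefore need not hold for the real comparison.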

Results

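Gene expression was measured by RNA sequencing in 3 control and 3 BCL6B-overexpressing libraries of U937 cells. The study asks what BCL6B, a zinc finger protein related to the transcriptional repressor BCL6, does in acute myeloid leukaemia cells, and its title names GGT5 and MAPK signalling. Depth was even, with 16481014 to 17627289 reads in listed genes in the controls and 17095256 to 18870186 with overexpression. Libraries separated by group along the first principal component of log2(FPKM + 1), which held 43.9% of the variance. Pearson correlations across genes were 0.985 to 0.987 within groups and 0.975 to 0.977 between them. Genes are not independent replicates, so these correlations are descriptive. Every pair of libraries differed by more than sampling noise, with a chi-square per gene of 2.37 or more, so no library was counted as a copy of another.

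BCL6B (ENSG00000161940, GRCh38 chromosome 17, 7023020 to 7030290, plus strand) had no read in any control and 1215 to 1712 reads per library with overexpression. Its level there was 16.7 ± 2.52 FPKM (SD, n = 3). Over the control group a count of 0 allows 3 counts, so BCL6B was at least 1311-fold higher (limma adjusted p = 1.6e-05). GGT5 (ENSG00000099998, chromosome 22, 24219654 to 24245142, minus strand) encodes a gamma-glutamyltransferase family enzyme that acts on leukotriene C4 and glutathione. It fell from 2.38 ± 0.0816 to 1.09 ± 0.161 FPKM (SD, n = 3 per group), or to 45.9% of the control mean (log2 change -0.69, SE 0.0853, limma adjusted p = 0.00408). All 3 overexpression libraries, with 111 to 138 GGT5 reads, lay below the controls, with 252 to 270. The exact permutation p was 0.1 for both genes, the smallest the design allows. BCL6 (ENSG00000113916, chromosome 3, 187721377 to 187745727, minus strand) was at 0.181 FPKM in controls and 0.190 FPKM with overexpression, below the filter, with an exact permutation p of 0.7. No transcript of another gene matched BCL6B or GGT5 by the criteria used for near-identical copies.

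**Figure D1:**
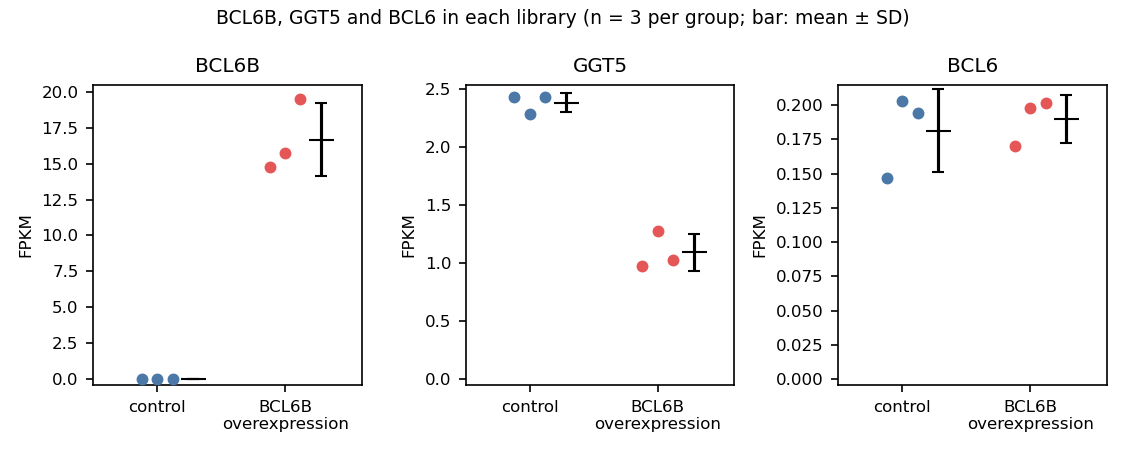
FPKM of BCL6B, GGT5 and BCL6 (y axes, each from 0) in the 3 control and 3 overexpression libraries; points are libraries and the bar beside them is the mean ± SD. BCL6B was at 0 in the controls and at 14.8 to 19.5 FPKM with overexpression, GGT5 was lower in all 3 overexpression libraries, and the BCL6 values overlapped.

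Across the transcriptome, 1199 genes rose and 1488 fell (limma on log2(FPKM + 1), 2687 of 14662 tested at the adjusted threshold of 0.05). Of these, 64 rose and 43 fell by at least 1 on the log2(FPKM + 1) scale, a count of 107 that was 310 with a pseudocount of 0.1, 187 with 0.5, 247 after TPM rescaling, 391 with voom and 69 among genes of at least 200 bases. RGS16, a regulator that shortens G protein signalling, rose 6.19-fold from 10.1 ± 0.890 to 62.5 ± 0.456 FPKM (SD, n = 3, log2 change 2.52, limma adjusted p = 1.6e-05). The cytokine TNF rose 4.08-fold to 82.2 ± 5.42 FPKM. EPX, which encodes eosinophil peroxidase, rose 3.75-fold. HES1, a Notch target that acts as a repressor, rose 4.55-fold. UCN2, KLHDC7B, HOXB7 and the stress-response factor ATF5 were also among the genes that the fixed rule takes for their rise, at 5.50-fold, 3.86-fold, 5.89-fold and 2.80-fold. Among the genes that the fixed rule takes, the largest fall on the log2(FPKM + 1) scale was that of DEFA4, a neutrophil defensin, to 5.03 ± 0.585 from 16.4 ± 2.70 FPKM (log2 change -1.52, limma adjusted p = 0.000944). SIGLEC12, MNDA, a nuclear antigen of myeloid cells, and DHRS9 fell to 0.307, 0.401 and 0.309 of their control means. DEFB1 and the metallothioneins MT2A and MT1X fell to 0.377, 0.449 and 0.427. CYTL1, the chaperone HSP90AA1 and DMXL2 fell to 0.456, 0.487 and 0.475. The 3 libraries of each group did not overlap for 40% of tested genes, where chance gives 10%. Leaving out 1 library lowered the number of changed genes to 1276 without control replicate 1, 1738 without control replicate 2, 1222 without control replicate 3 and 1333 without overexpression replicate 2. Without the filter on low values it was 1588.

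**Figure D2:**
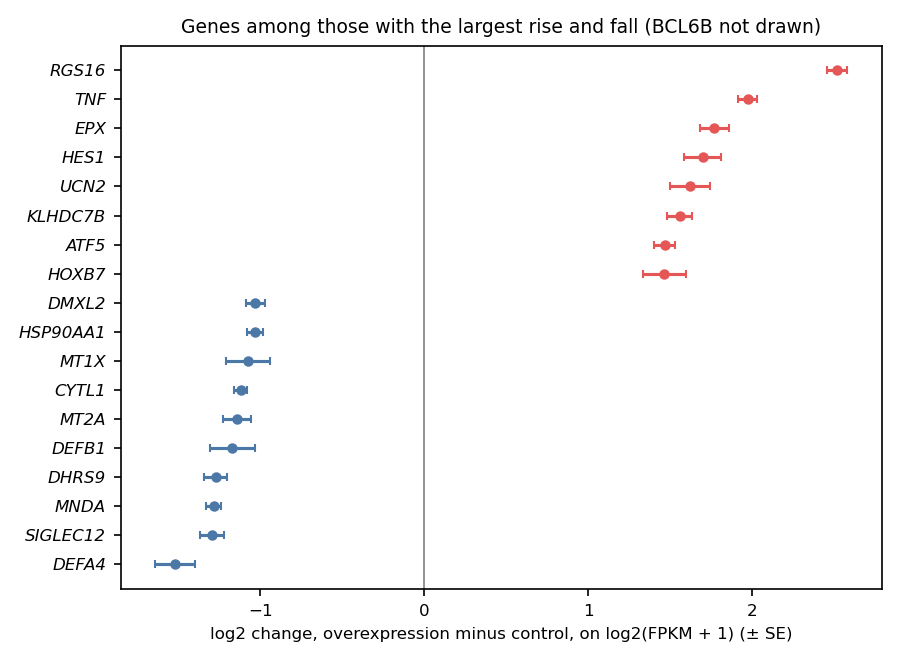
Log2 change, overexpression minus control, on log2(FPKM + 1) (x axis) of genes among those with the largest rise and fall under the fixed rule (y axis), BCL6B left out; points are estimates from 3 libraries per group and bars are ± SE. Values run from -1.52 for DEFA4 to 2.52 for RGS16.

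To ask which processes moved, 34 fixed gene lists were tested with camera, and 15 had a direction at the adjusted threshold, 11 up and 4 down. Some called lists share members, so these calls are not independent of each other. With an estimated in place of the preset correlation none of the 15 calls held, and 8 lists had an unadjusted p under 0.05. The adjusted p with an estimated correlation is given beside each called list below. The share of mitochondrial reads, which can reflect RNA quality or a change in expression, differed slightly between groups. Mitochondrially encoded genes took 4.17% to 4.44% of reads in controls and 4.49% to 4.97% with overexpression.

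Genes known as targets or feedback regulators of ERK, the kinase at the end of the RAS-RAF-MEK branch of MAPK signalling, rose in 14 of 30 cases and 0 fell, 17 rose when adjusted over the list alone, and the median log2 change was 0.23 (camera adjusted p = 4.25e-06, adjusted p = 0.0884 with an estimated correlation). JUN rose 2.30-fold to 14.1 ± 0.634 FPKM, and DUSP6, a phosphatase that switches ERK off, rose 1.54-fold to 35.5 ± 0.515 FPKM. PLAUR, the urokinase receptor, rose 1.85-fold and CCND1, which encodes cyclin D1, rose 1.59-fold. Receptors and growth factors upstream of MAPK moved the same way, with 6 of 16 rising and 0 falling (camera adjusted p = 0.00167, adjusted p = 0.254 with an estimated correlation), and 7 rose and 2 fell when adjusted over the list alone. FLT1, FGFR1, PDGFA and IL3RA rose 2.33-fold, 1.54-fold, 2.43-fold and 1.69-fold, from control levels of 0.889, 2.27, 0.832 and 3.41 FPKM. The components of the MAPK cascade did not move as a list, with 7 rises and 4 falls among 55 (camera adjusted p = 0.338), also when adjusted over the list alone. MKNK2, a kinase downstream of ERK, rose 1.74-fold and RRAS 2.32-fold, while MAPK14, which encodes p38 alpha, fell to 0.755 of control.

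Of 26 inflammatory and NF-kB response genes 12 rose and 0 fell, with 13 rising and 1 falling when adjusted over the list alone (median log2 change 0.24, from 0.16 without the filter to 0.46 at a mean FPKM of at least 1, camera adjusted p = 5.02e-06, adjusted p = 0.0884 with an estimated correlation). Besides TNF, the adhesion molecule ICAM1 rose 3.05-fold to 6.47 ± 0.848 FPKM, the chemokine CXCL8 rose 2.02-fold to 49.3 ± 6.04 FPKM, and TRAF1 rose 2.47-fold. The interferon response list had 2 rises and 1 fall among 33, the same when adjusted over the list alone (camera adjusted p = 0.622). Those were IRF7 and CXCL10, at 12.8 and 1.69 FPKM from 8.52 and 0.745 FPKM, and MX2, down to 0.807 of control. Each of these lost its call when 1 library was left out, IRF7 without control replicate 1, CXCL10 without overexpression replicate 2 or 3, and MX2 without any 1 of the controls or without overexpression replicate 2, with adjusted p up to 0.0517, 0.0563 and 0.0777. In the JAK-STAT feedback list 1 of 14 genes rose and 0 when adjusted over the list alone (camera adjusted p = 0.622). That was BCL3, up 2.10-fold, which lost its call in every leave-one-out fit except that without control replicate 1, with adjusted p up to 0.0885.

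Genes of hypoxia and glycolysis rose in 15 of 30 cases and fell in 2, or 16 and 2 when adjusted over the list alone (median log2 change 0.23, camera adjusted p = 4.64e-06, adjusted p = 0.133 with an estimated correlation). VEGFA, the vascular growth factor, rose 2.19-fold to 37.9 ± 1.47 FPKM. PFKFB3, a driver of glycolysis, the glucose transporter gene SLC2A3 and P4HA1 rose 1.71-fold, 1.52-fold and 1.63-fold. Among 14 angiogenesis factors 6 rose and 0 fell, or 7 and 0 when adjusted over the list alone (camera adjusted p = 0.00109, adjusted p = 0.261 with an estimated correlation). VEGFA, CXCL8, FLT1 and PDGFA led this list. Each also belongs to another list called up, of hypoxia, inflammatory or receptor genes, so the angiogenesis call is not separate evidence. In cell adhesion and migration 13 of 27 rose and 2 fell, or 15 and 2 when adjusted over the list alone (camera adjusted p = 8.86e-05, adjusted p = 0.102 with an estimated correlation). With ICAM1 and PLAUR, the intermediate filament gene VIM rose 1.32-fold to 158 ± 7.61 FPKM and ICAM3 rose 1.51-fold.

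Of 53 G2/M and mitosis genes 23 fell and 0 rose, or 35 fell and 2 rose when adjusted over the list alone (median log2 change -0.20, camera adjusted p = 2.07e-07, adjusted p = 0.102 with an estimated correlation). CENPF, DLGAP5, the mitotic kinase gene AURKA and CENPE fell to 0.724, 0.686, 0.778 and 0.745 of control. Of 44 genes of G1/S and DNA replication 10 rose and 2 fell, or 11 and 3 when adjusted over the list alone (median log2 change 0.0609, 0.0321 after TPM rescaling and 0.0375 without overexpression replicate 1, camera adjusted p = 0.0192, adjusted p = 0.143 with an estimated correlation). RRM2, FEN1 and CCNE1, which encodes cyclin E1, rose 1.53-fold, 1.37-fold and 1.78-fold, and CDC6 rose from 5.45 to 8.73 FPKM. Of 18 cyclins, CDKs and CDK inhibitors 6 rose and 1 fell, also when adjusted over the list alone (camera adjusted p = 0.00599, adjusted p = 0.254 with an estimated correlation). The members that rose act in opposite ways on the cycle. CDKN1A, which encodes the CDK inhibitor p21, rose 5.01-fold from 0.493 to 2.47 FPKM, and the inhibitor gene CDKN2D 1.42-fold, while CCND1 and CCND3 encode cyclins that promote it. CCND3 rose 1.16-fold and lost its call in every leave-one-out fit except that without overexpression replicate 1, with adjusted p up to 0.0984.

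Among p53 target genes 3 of 19 rose and 1 fell, also when adjusted over the list alone (camera adjusted p = 0.0731, 0.0476 without control replicate 1 and 0.0376 without the filter on low values). These rises were CDKN1A, the pro-apoptotic gene BBC3 at 1.58-fold and BTG2 at 3.15-fold, and the fall was AEN, named outside the rule. Pro-apoptotic genes had 6 rises and 2 falls among 29, the same when adjusted over the list alone (camera adjusted p = 0.406), with BMF up 2.29-fold and TNFSF10, which encodes TRAIL, down to 0.592 of control. Anti-apoptotic genes had 2 rises and 2 falls among 15, or 4 and 2 when adjusted over the list alone (camera adjusted p = 0.703). TRAF1 rose, while BAG1 fell to 0.768 and BIRC2 to 0.838 of control, the last losing its call without any 1 of the controls or without overexpression replicate 2, with adjusted p up to 0.0840. BCL2A1, named outside the rule, rose 1.43-fold.

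In the heat shock list of protein folding genes 8 of 13 fell and 0 rose, or 9 and 1 when adjusted over the list alone (median log2 change -0.36, camera adjusted p = 0.00026, adjusted p = 0.261 with an estimated correlation). HSP90AA1 fell from 242 ± 6.51 to 118 ± 5.30 FPKM, HSPA8 from 136 ± 4.27 to 69.8 ± 1.86 FPKM, and HSPH1 and HSPE1 to 0.580 and 0.612 of control. MYC targets and ribosome biogenesis genes fell in 19 of 30 cases with 0 rising, or 20 and 0 when adjusted over the list alone (median log2 change -0.28, camera adjusted p = 2.07e-07, adjusted p = 0.0926 with an estimated correlation). GNL3, UTP20, HSPD1 and RRP12 fell to 0.747, 0.604, 0.776 and 0.680 of control. The list of the integrated stress response and unfolded protein response had 8 rises and 11 falls among 29, or 9 and 11 when adjusted over the list alone, with a median of -0.0388, a mean of 0.0373 and camera pointing down (adjusted p = 0.977). ATF5 and TRIB3 rose 2.80-fold and 2.07-fold, while HSPA5, the chaperone BiP of the endoplasmic reticulum, fell to 0.697 of control.

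Cytosolic ribosomal protein genes were slightly higher as a list (median log2 change 0.17, 0.0739 after quantile normalization and 0.108 without overexpression replicate 2, camera adjusted p = 1.05e-05, adjusted p = 0.617 with an estimated correlation), yet 1 of 48 rose and 0 fell, also when adjusted over the list alone. RPL28 rose 1.24-fold. RPS27 and RPL12 did not pass, at 1.43-fold and 1.17-fold of control, with adjusted p of 0.0682 and 0.109. Across alternatives the adjusted p ranged from 0.00188 to 0.184 for RPS27 and from 0.0142 to 0.297 for RPL12, which passed without control replicate 2, at 0.03. Both passed with the replicate number as a block, at 0.0207 and 0.0479, with library weights and with voom. The mean log2 level of the list was 8.41 to 8.66 in control libraries and 8.59 to 8.80 with overexpression, so the groups overlapped. It was higher with overexpression within each same-numbered pair, though the labels do not say that the numbers mark pairs. Of 13 mitochondrially encoded genes 4 rose and 0 fell, or 5 and 0 when adjusted over the list alone (median log2 change 0.26, camera adjusted p = 0.00209, adjusted p = 0.42 with an estimated correlation, and adjusted p = 0.176 with a median of 0.106 after quantile normalization). The median was 0.156 without overexpression replicate 2. MT-ND1, MT-ND2, MT-ND3 and MT-CYB rose 1.53-fold, 1.36-fold, 1.87-fold and 1.24-fold, and MT-CYB lost its call without control replicate 1 or 3, with adjusted p up to 0.0653, and after quantile normalization, at 0.272. Without the filter on low values MT-ND1, MT-ND2 and MT-CYB lost their calls, at adjusted p of 0.0742, 0.136 and 0.103. Nuclear genes of oxidative phosphorylation had 1 rise and 2 falls among 41, and 0 of either when adjusted over the list alone (camera adjusted p = 0.111). The list passed downward without control replicate 1 or 3 or overexpression replicate 2, at adjusted p of 0.0448, 0.0465 and 0.00773, after TPM rescaling, at 0.0436, and without the filter on low values, at 0.0117. ATP5MC1, UQCRC2 and NDUFB5 stood at 0.763, 0.897 and 1.17 of control. ATP5MC1 lost its call without control replicate 1, UQCRC2 without any 1 library and NDUFB5 in all but the fit without overexpression replicate 3, with adjusted p up to 0.0524, 0.142 and 0.113.

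Of 15 granule genes of the granulocytic lineage 9 fell and 2 rose, or 9 and 3 when adjusted over the list alone (median log2 change -0.40, camera adjusted p = 0.0341, adjusted p = 0.261 with an estimated correlation). CTSG, which encodes cathepsin G, fell from 44.2 ± 5.31 to 21.7 ± 1.88 FPKM, SRGN from 1881 ± 143 to 1063 ± 70.4 FPKM, and MS4A3 to 0.637 of control. The rises were EPX and PRG2, the latter named outside the rule. Without the filter on low values the median was -0.0176. The list's call was lost without control replicate 2 and without overexpression replicate 3, at adjusted p of 0.0622 and 0.0594, with a pseudocount of 0.1 and with library weights, at 0.052 and 0.0642. Markers of monocyte and macrophage differentiation had 4 rises and 2 falls among 25, also when adjusted over the list alone (camera adjusted p = 0.315). LYZ, the lysozyme gene, and CEBPD fell to 0.589 and 0.666 of control. Leukaemia stem and HOX genes had 3 rises and 3 falls among 13, also when adjusted over the list alone (camera adjusted p = 0.496). GATA2 rose 2.32-fold, while MYB and CD33 fell to 0.721 and 0.794 of control.

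GGT5 was 1 of 2 genes that fell among 31 of gamma-glutamyl and glutathione metabolism, with 0 rising, also when adjusted over the list alone. The other was SLC7A11, the cystine transporter gene, at 0.652 of control. The list had no direction (camera adjusted p = 0.977), and its median and mean, -0.00528 and -0.0320, differed in sign from the camera test. The study names GGT5 in its title, so its place in the list is not independent evidence. Leukotriene and eicosanoid genes had 5 falls and 2 rises among 14, also when adjusted over the list alone (camera adjusted p = 0.113), with PLA2G4A, the phospholipase that releases arachidonic acid, at 0.517 and PTGES2 at 0.762 of control. Cholesterol and fatty acid synthesis had 4 rises and 6 falls among 31, or 4 and 8 when adjusted over the list alone (camera adjusted p = 0.338). FDFT1 and ACACA fell to 0.729 and 0.706 of control and FADS1 rose 1.45-fold. Of 7 lipid efflux and LXR targets 1 fell, also when adjusted over the list alone (camera adjusted p = 0.786, median 0.00156 and mean -0.0136). It was ABCA1, at 0.666 of control, which lost its call without control replicate 1 or overexpression replicate 2, at adjusted p of 0.0566 and 0.0547.

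Among 29 genes of the BCL6 family, its corepressors and reported BCL6 targets, 6 rose, the introduced BCL6B included, and 2 fell, also when adjusted over the list alone (camera adjusted p = 0.315). CDKN1A and CD69 were among the rises, CD69 by 1.99-fold. Of 15 genes of the DNA methylation machinery 3 rose and 0 fell, also when adjusted over the list alone (camera adjusted p = 0.0987, and 0.0402 without the filter on low values), DNMT3B by 1.51-fold, UHRF1 by 1.24-fold and DNMT3L by 3.16-fold from 0.240 FPKM. UHRF1 and DNMT3L lost their calls in 5 of 6 leave-one-out fits, all but those without overexpression replicate 1, with adjusted p up to 0.0627 and 0.112. MHC class I genes had 1 rise and 1 fall among 7, also when adjusted over the list alone (camera adjusted p = 0.771). NLRC5 fell to 0.733 of control and TAPBP rose from 17.8 to 21.4 FPKM, and TAPBP lost its call without any 1 of the controls or without overexpression replicate 2, with adjusted p up to 0.0753. The MHC class II list had 1 tested member, HLA-DMA, at 0.936 of control (adjusted p = 0.838), named outside the rule.

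Markers of other cell types were measured in the same libraries. Of 5 erythroid and megakaryocyte markers 3 rose and 0 fell, also when adjusted over the list alone (camera adjusted p = 0.00241, adjusted p = 0.133 with an estimated correlation). TFRC, the transferrin receptor gene that dividing cells also use, rose 1.61-fold to 50.9 ± 2.07 FPKM. GATA1 and ITGA2B rose 2.59-fold and 2.13-fold but from 0.544 and 0.705 FPKM, and lost their calls in 3 and 4 of the 6 leave-one-out fits, with adjusted p up to 0.0643 and 0.0829. Those were without control replicate 3 and overexpression replicates 1 and 2 for GATA1, and without control replicates 1 and 3 and overexpression replicates 2 and 3 for ITGA2B. GP1BA, at 0.559 FPKM in controls and 0.886 FPKM with overexpression, did not pass (adjusted p = 0.298). Of 4 T and NK cell markers 3 rose and 0 fell, or 4 and 0 when adjusted over the list alone. TRAC stood at 35.1 ± 2.21 FPKM in controls and 62.5 ± 2.85 with overexpression, NKG7 at 61.2 and 70.5 and NCAM1 at 0.306 and 0.905. NKG7 lost its call without control replicate 1 or 3 or overexpression replicate 2, and NCAM1 without overexpression replicate 2, with adjusted p up to 0.0735 and 0.0582. Of 5 B and plasma cell markers none passed, nor when adjusted over the list alone (camera adjusted p = 0.978, median -0.0583 and mean 0.00215). None passed among 4 endothelial markers and 2 markers of epithelial or packaging cells, and 1 of 3 fibroblast markers rose, with the same counts when adjusted over the list alone. That was TAGLN, at 0.821 and 1.74 FPKM.

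Of 5 long nuclear and small RNAs 2 rose and 0 fell, or 3 and 0 when adjusted over the list alone (camera adjusted p = 0.0604). The list passed without control replicate 2 or overexpression replicate 3, at adjusted p of 0.0324 and 0.0154, and in 5 other settings. SNHG1 rose from 175 to 218 FPKM and NEAT1 rose 1.24-fold, NEAT1 losing its call without control replicate 1 or 3 or overexpression replicate 2, with adjusted p up to 0.0617. Of 4 replication-dependent histone genes 1 fell, also when adjusted over the list alone. It was HIST1H2AC, at 0.594 of control, which lost its call without control replicate 2 or 3 or overexpression replicate 3, with adjusted p up to 0.0698.

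**Figure D3:**
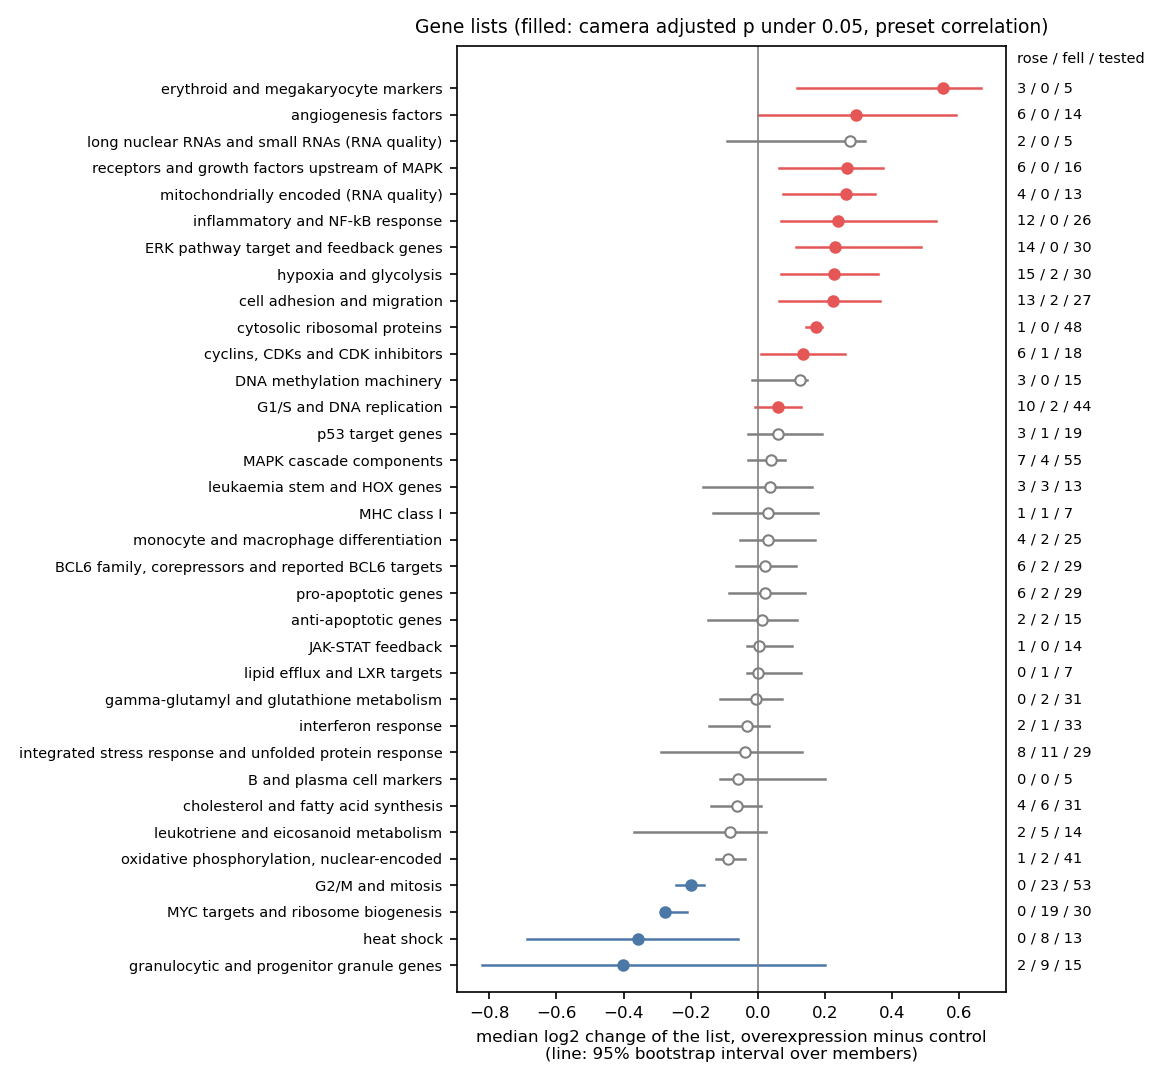
Median log2 change of the members of each tested list (x axis, overexpression minus control, 3 libraries per group) for 34 gene lists (y axis); points are medians, lines are 95% bootstrap intervals over members, and filled points passed camera with the preset correlation. The numbers at the right count members that rose, fell and were tested. Medians run from -0.40 for granule genes to 0.55 for erythroid and megakaryocyte markers (-0.0176 and 0.236 without the filter on low values), and no call held with an estimated correlation.

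Of the 115 tested genes that the rule takes, 12 may share reads with other annotated genes. BCL6 and genes named outside the rule were not checked. ATF5, DUSP6, ICAM1, ICAM3 and LYZ overlap antisense genes over at least 20% of their exons, and RRM2 overlaps a gene on its own strand. SLC2A3, UHRF1, DNMT3L, RPL12, MT-ND1 and MT-ND2 have copies of at least 98% identity. Because the use of strand and of reads with several matches is not given in the sources used here, the values of these genes are uncertain.

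Some calls given above also depended on other settings. Without the filter on low values BCL3, CXCL10, DNMT3L, GATA1, HIST1H2AC, ITGA2B, NDUFB5 and UHRF1 lost their calls, with adjusted p up to 0.0895. After TPM rescaling CCND3, NDUFB5, TAPBP, UHRF1 and UQCRC2 lost theirs, with adjusted p up to 0.0826. BCL3 and BIRC2 did so with the correction for GC content and length, at 0.0516 and 0.0605, an alternative chosen after seeing the data. With the replicate number as a block BCL3, BIRC2, NDUFB5 and UQCRC2 lost theirs, with adjusted p up to 0.0749. Without the mean-variance trend CCND3, NDUFB5 and UQCRC2 did, with adjusted p up to 0.0899. UQCRC2 also lost its call with median-ratio scaling and quantile normalization, at 0.0567 and 0.069, and DNMT3L with a pseudocount of 0.1, at 0.055.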

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

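The spline correction and the restriction to genes of at least 200 bases were chosen after seeing the data, and the other alternatives before. BCL6B and GGT5 passed in all 20 settings, with log2 changes of 4.02 to 11.3 and of -1.13 to -0.65. The fitted BCL6B values depend on the offset added to 0 and are no bound. No named gene or list that passed turned its direction, while medians of some lists without a call crossed 0. Among the other named genes, 2031 of the alternative values stayed on their side of the threshold, 97 lost the call and 14 gained it. Of the list values with the preset correlation, 625 stayed, 5 lost the call and 15 gained it. The erythroid list had too few members to be run at a mean FPKM of at least 1. The 2687 changed genes became 1588 without the filter on low values (716 higher, 872 lower), where 30382 genes were tested. At an adjusted threshold of 0.1 they were 4054, and 107 with an absolute log2 change of at least 1. This last count was 310 with a pseudocount of 0.1 and 187 with 0.5, which shrink low genes less, 247 after TPM rescaling, 391 with voom on the recovered reads and 69 among genes of at least 200 bases, where short genes are left out. TPM rescaling raised every value above 0, because FPKM summed to only 272068 to 292341 per library. The added 1 therefore shrank low genes less there too. The causes of the other differences were not tested. Leaving out 1 library gave 1222 to 2272 changed genes, 604 to 1014 higher and 618 to 1258 lower. With 2 libraries in a group the fit has fewer samples. Voom called 3714 genes, of which 2528 were among the 2687. The median log2 change of all tested genes, -0.0182, was -0.0521 after TPM rescaling and -0.00826 with median-ratio scaling. TPM rescaling gave 890 higher and 1521 lower genes, and quantile normalization 1299 and 1331. Of the 15 lists with a direction, 0 held with an estimated correlation in camera, where 8 had an unadjusted p under 0.05. That setting changed the degrees of freedom as well as the correlation.

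The replicate numbers shared by the groups gave at most a weak sign of pairing. Deviations from the group means correlated at -0.00189 to 0.11 between same-numbered libraries, over 0.1 in 1 of 3 pairs. Between other-numbered libraries of different groups they correlated at -0.0909 to 0.0386, and 4 of 6 libraries correlated best with their own number. On the second principal component, with 16.2% of the variance, control replicate 2 and overexpression replicate 2 lay at 18.4 and 10.8. All other libraries were on the opposite side. With the replicate number as a block, 2328 genes changed, 2052 of them among the 2687, and 15 lists had a direction. Depth limits genes with few reads. At 16481014 to 18870186 reads in listed genes, GGT5 rests on 111 to 270 reads and BCL6 on 16 to 24 per library.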

Other observations

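The tests of the interferon list, of the G1/S list, of the mitochondrially encoded genes across libraries and of the bZIP family, and the correction for GC content and length, were chosen after the results were seen, as were the comparisons of transcription factor families below.

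Among 886 tested transcription factor genes, grouped by the family column of the deposited table, 3 of 26 families differed in how often their members rose (two-sided Fisher's exact test, adjusted over the families). Of 39 bZIP genes 12 rose, or 30.8%, against 8.74% of the 847 others (adjusted p = 0.00188). Among them were ATF5, JUND, JUN, BATF3, JUNB, FOSL1, NFE2, FOS, CREBZF, ATF4 and NFE2L1, all but ATF5 and JUN named after their values were seen. JUND stood at 19.9 FPKM in controls and 55.7 FPKM with overexpression. Another 4 fell, BATF, XBP1, NFIL3 and CREB3L2, also named after their values were seen. Of 7 genes of the RXR-like family 4 rose, NR2F1, RXRA, NR2C2 and NR2F6, named after their values were seen (adjusted p = 0.02). C2H2 zinc finger genes rose less often, in 17 of 398 cases or 4.27% against 14.1% of the others (adjusted p = 1.45e-05), while 7.79% fell against 9.84% (adjusted p = 1). Outside protein-coding genes, 482 further genes changed. Among 21 mitochondrial transfer RNA genes 5 rose and 0 fell. The libraries were selected with oligo(dT) beads, and a rise and a difference in RNA quality cannot be told apart for these genes.

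The rise of bZIP genes was weighed against the makeup of the comparison and overlap with the ERK list. It was found with the same test, so chance stays open. Because C2H2 genes make up much of the comparison and rose rarely, it was repeated without them, giving 12.7% of 449 genes (two-sided Fisher's exact test p = 0.0062). The ERK list holds 4 of the 12, which were all of its tested bZIP genes, and 8 of the 35 bZIP genes outside it rose. The repeat without C2H2 genes still included these 4. Whether bZIP genes outside the ERK list rose more often than families without C2H2 genes was not tested. The family comparisons were not repeated after the correction for GC content and gene length, so such a trend stays open for them. No biological explanation was tested.

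The ERK target, inflammatory, heat shock, ribosome biogenesis and G2/M lists were weighed against a trend with GC content and gene length. After the correction, which moved single genes by an SD of 0.0383, the medians were 0.22 for ERK targets, 0.23 for inflammatory genes, -0.34 for heat shock, -0.26 for ribosome biogenesis and -0.18 for G2/M genes, and all 5 intervals excluded 0 with the lists still called, so such a trend is not the whole cause. An interferon response to the vector in the overexpression group alone would raise the interferon list with the inflammatory genes. The median of the interferon list was -0.0316, with an upper bound of 0.0328. That criterion was set after the list had been seen, and a response shared by both groups would not show here. Fewer cycling cells alone would lower G1/S genes with G2/M genes, but the G1/S median was 0.0609, with a lower bound of -0.00841, above the G2/M interval. This was asked after both lists had been seen. Fewer cycling cells together with a separate rise of some G1/S genes would give the same values and stay open. Intervals are over members, which are not independent, so the spread between libraries stays open as a contributor, as does a shift between cycle phases. No list call held with an estimated correlation. For ERK targets and inflammatory genes that correlation, -0.0262 and -0.00434, was below the preset 0.01. Their lost calls therefore came with the fewer degrees of freedom of that setting and do not show that members moved together. For heat shock, ribosome biogenesis and G2/M genes it was higher, at 0.231, 0.0286 and 0.0309.

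The rise of the ribosomal protein and mitochondrially encoded lists was weighed against spread between libraries. The corrected ribosomal protein median was 0.17, so a trend with GC content and length is not the whole cause. The lowest overexpression library lay -0.0696 from the highest control on the mean log2 level of that list, so the groups overlapped, as spread between libraries predicts. For mitochondrially encoded genes the gap was 0.10, smaller than the SD of 0.12 in the overexpression group. A rise and a difference in RNA quality between libraries cannot be told apart for this list.

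Splitting the 6 libraries into 3 and 3 can be done in 10 ways, too few for a share under 0.05. The real split, 1 of the 10, gave 2687 changed genes and 15 lists with a direction, and the highest of the others gave 2 genes and 7 lists. Every other split put libraries of both groups on each side. The group difference then added to the spread within each side, which lowers the count of genes by design. These counts are therefore no measure of what libraries without a group difference would give.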
